A study of Solanum lycopersicum with 12 samples.

How the data were processed

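Leaves of 3 tomato lines, named VF36, D51 and Son1 in the labels, were inoculated with tobacco mosaic virus (TMV, an RNA virus applied by rubbing leaves), mock inoculated or left untreated, and were collected 1 h later. Per the labels, resistant, susceptible and hypersusceptible mutant plants were used, without a statement of which name belongs to which, so the lines are called by name here. Plants were about 5 weeks old and were kept at 25 °C with 16 h of light and 8 h of darkness. Each RNA sample came from 2 pooled plants, and 130 µg of total RNA was used. The 12 arrays form 6 groups of 2 arrays, with 1 group per line for mock RNA against untreated RNA (called mock arrays) and 1 group per line for TMV RNA against mock RNA (called TMV arrays). Mock RNA was labelled with Cy5 on all 12 arrays and the other RNA with Cy3, so no dye was swapped and a dye bias of a clone cannot be separated from its change within 1 kind of array. In D51 the mock arrays and the TMV arrays of a replicate number list the same mock extract. In VF36 and Son1 the listed extracts differ.

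The deposited values are log2 ratios of the 2 channels of an array. The submitters' processing notes name limma without a version, and other steps and the filter that left spots blank are not given in the sources used here. The log base was read from the values: 2 to the power of the value was a ratio with 2 decimals for 100% of the values, within 0.0015 on the log2 scale. The medians of the arrays lay between -0.013 and 0.043, so scale and centring fit log2 ratios normalized within arrays. Intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

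The direction of the deposited ratios is not given in the sources used here and is not settled. Signs are printed under the order of the channels in the labels (channel 1 over channel 2), which reads the mock arrays as mock over untreated and the TMV arrays as TMV over mock. The dye convention of limma (Cy5 over Cy3) gives the same sign on mock arrays and the opposite sign on TMV arrays. The titles name untreated before mock and mock before TMV, and ratios in that order would invert every array, so that each higher becomes lower while the counts stay. The design fixed before the data were examined named Cy5 over Cy3 unless the correlation of the arrays spoke against it. With mock RNA in Cy5 on every array, that reading lets mock and TMV arrays vary together, but of 6528 clones with a value on all 12 arrays 174 had opposite signs on the 6 mock and the 6 TMV arrays and 3 had the same sign on all 12. The order of the channels was taken for this reason, after those correlations were seen and before any test. The counts do not decide it, since under Cy5 over Cy3 opposite signs also arise if mock leaves lie between untreated and TMV leaves. For TMV against untreated the replicates of VF36 correlated with r = -0.535 under the order of the channels and 0.738 under Cy5 over Cy3. Those of D51 had 0.436 and 0.261, and those of Son1 0.207 and 0.361. In VF36 mock replicate 1 and TMV replicate 2 mirrored each other (r = -0.843), which lowers the first VF36 value and raises the second. The VF36 values therefore do not decide the reading. Taking the order of the channels in place of Cy5 over Cy3 lowers the calls for TMV against untreated over 3 lines from 550 to 0. The Cy5 over Cy3 reading is given beside each comparison of the TMV arrays. Arrays of 1 dye orientation also correlated below 0, with r = -0.31 across clones between VF36 mock replicate 1 and D51 mock replicate 1, which is a further reason to treat each direction as open.

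The table lists 32448 spots. In 905 of 905 annotated clones the spots of a clone lay 844 or 1859 rows apart, and this rule gave 15360 clones with 2 spots each, while the other 1728 spots held no value. The 2 spots were averaged, using the spot present where 1 was blank. A shift of the pairing by 1 row lowered the correlation of paired spots to -0.001 and 0.004. Of the clones, 10138 had a value on at least 1 array and 6528 on all 12. The probe table, made from potato sequences, gave 1 gene symbol for 815 clones, several for 90 and none for 14455. Clones with several symbols were not named. The 430 symbols include 91 that are not LOC identifiers. None of its 475 gene identifiers (0 matched) occurs in the tomato gene table, so the symbols are kept as given, and functions of LOC identifiers are not stated.

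Values were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 6 group means over all 12 arrays so that groups of 2 share an estimate of the spread. A clone entered a contrast if it had a value on every array of the groups in it. The contrasts were mock against untreated, TMV against mock, and TMV against untreated through mock (the mock-array mean plus the TMV-array mean, in which a dye bias of a clone cancels if the reading of the TMV arrays is right and adds up if it is wrong), each per line and as the mean of 3 lines, and an F test of the line differences in the mock response and in the TMV response. If the TMV arrays are read the wrong way, the third contrast instead sets mock against both untreated and TMV leaves. A clone was called at a Benjamini-Hochberg adjusted p under 0.05. The named genes are, per contrast, the 10 largest positive and 10 largest negative log2 changes among called clones with 1 symbol and the same sign in both replicates of each line, with 1 clone per symbol. Where fewer than 5 passed, the 5 highest and 5 lowest moderated t values are given as not passing, and for line differences the 5 largest F values. Members of gene lists with the smallest p, at most 4 per list, and up to 2 unnamed clones per direction are given too. Tests of gene lists used camera with a correlation of 0.01 and lists of at least 5 clones. The 19 lists fixed before the data were examined were largely written as protein names but were matched to symbols alone. Of these lists 5 had a clone measured in at least 1 contrast (4 in mock against untreated over 3 lines) and 0 could be tested. A further 6 lists were written from the symbols before fold changes were seen, and 5 of them were tested in 60 combinations of list and contrast. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

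The fit was tested on simulated data with the spread of 6528 clones and 100 clones changed by a log2 of 1 and 100 by a log2 of 2. For mock against untreated over 3 lines it recovered 82 and 98 of them, with 8 false calls. For TMV against mock over 3 lines it recovered 79 and 97, and for TMV against untreated 60 and 95. In a single line it recovered 42 and 92 for mock against untreated in VF36 and 16 and 66 for TMV against untreated in D51. Line differences in the TMV response were recovered for 9 and 57. False calls in these other tests numbered between 1 and 11. The simulated values were independent between clones and arrays, with 1 spread per clone on all arrays. The spread over clones of the real arrays ranged from 0.264 on Son1 TMV replicate 2 to 0.812 on VF36 mock replicate 1. Real arrays also correlated across clones, with r from -0.843 to 0.685, so these rates need not hold for them.

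Alternatives fixed before the data were examined were centring, centring with scaling, other filters on missing values, fits on the arrays of a contrast alone, replicate blocks, a robust prior, a 2-fold threshold, the other reading of the TMV arrays, averaging clones of a symbol, an estimated correlation for lists, and leaving out each array. Array weights, spots tested singly and leaving out 2 VF36 arrays together were added after seeing the data. The labels give replicate numbers 1 and 2 in every group, which mark a shared mock extract in D51 and were not used as pairs in the fits. For TMV against untreated the counts of pairs and the correlations of replicates join the mock and the TMV array of the same number, although those of VF36 and Son1 list different extracts. Replicates are separate RNA samples, and whether they came from separate experiments is not stated, so p-values measure the spread between these samples.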

Results

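The expression of leaf transcripts 1 h after inoculation with tobacco mosaic virus was measured in 3 tomato lines, VF36, D51 and Son1, on 12 cDNA arrays with 2 colours. Each line had 2 mock arrays (mock against untreated RNA) and 2 TMV arrays (TMV against mock RNA). Between 7465 and 9665 clones had a value per array, and the 2 spots of a clone correlated with r between 0.712 and 0.946 on 11 arrays and with r = 0.286 on VF36 TMV replicate 1. The spread of the log2 ratios over clones averaged 0.624 ± 0.124 (SD, n = 6) on mock arrays and 0.465 ± 0.183 (SD, n = 6) on TMV arrays. Mock arrays are read as mock over untreated and TMV arrays as TMV over mock. Neither direction is settled, and values under another reading stand beside each comparison.

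**Figure D1:**
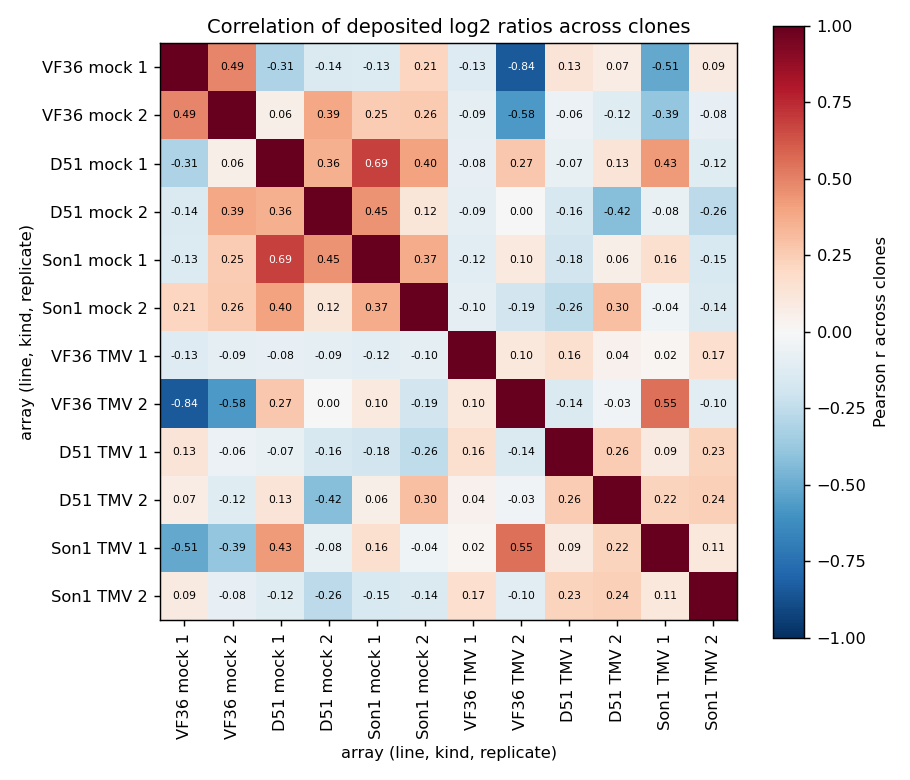
Pearson correlation across clones of the deposited log2 ratios between all pairs of the 12 arrays, with arrays by line, kind and replicate on both axes and colour from -1 to 1. VF36 mock replicate 1 and VF36 TMV replicate 2 have the lowest value, -0.843, and D51 mock replicate 1 and Son1 mock replicate 1 have 0.685.

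The first comparison asked what mock inoculation alone changed. Averaged over the 3 lines, transcripts of SKT3, a potassium channel, were lower in mock-inoculated than in untreated leaves by a log2 change of -0.80 ± 0.14 (SE, n = 6 arrays, adjusted p = 0.0193), and POTPRO1 by -0.95 ± 0.13 (adjusted p = 0.0145), each in 6 of 6 arrays. LOC102577613 stood at -1.30 ± 0.14 (adjusted p = 0.0124). Its mean was 2.32-fold lower in VF36, 2.83-fold in D51 and 2.25-fold in Son1. LOC102582822 (-1.25), LOC102577637 (-1.19), LOC102582373 (-1.10), LOC102583272 (-1.04), LOC102596122 (-1.02), LOC102577612 (-0.75) and LOC102577453 (-0.65) were also lower on every mock array. All 4 measured clones of LOC102596122 lay between -1.12 and -0.94, whereas 1 of 3 clones of LOC102582373 stood at 0.05 and 1 of 2 clones of LOC102583272 at 0.06. The 3 clones of LOC102577637 ranged from -1.19 to -0.16.

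Named transcripts that were higher after mock inoculation changed less. LOC102578519 was 1.49-fold higher, LOC102596994 1.48-fold, LOC102580103 1.46-fold and LOC102582711 1.43-fold, each on 6 of 6 mock arrays. LOC102603136, LOC102587260, LOC102584575 and LOC102577684 were between 1.39-fold and 1.42-fold higher. All 4 clones of LOC102578519, all 4 of LOC102580103 and all 5 of LOC102582711 were above 0. LOC102587499 was 1.44-fold higher by 1 clone, but its 6 clones ranged from -0.66 to 0.53 and their average was lower, at -0.28. Among unnamed clones, 147665 was 3.32-fold higher and 154107 was 3.63-fold lower.

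**Figure D2:**
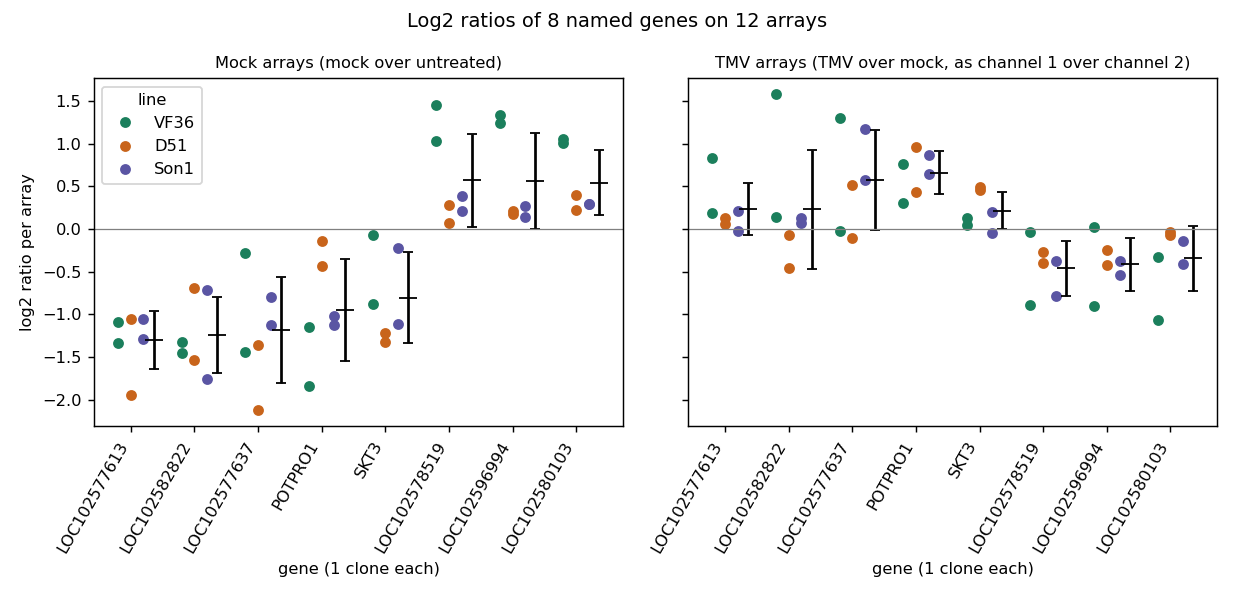
Log2 ratio per array (vertical axis) of 8 named genes, 1 clone each (horizontal axis), on the 6 mock arrays (left, mock over untreated) and the 6 TMV arrays (right, TMV over mock as channel 1 over channel 2). Points are arrays coloured by line, and bars are the mean and SD of 6 arrays. LOC102577613 lies between -1.94 and -1.06 on the mock arrays, and POTPRO1 has a mean of -0.95 on mock arrays and 0.66 on TMV arrays.

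In all, 489 of 7381 clones passed an adjusted p of 0.05 with limma, 221 higher and 268 lower, and 2131 had an unadjusted p under 0.05. Fewer clones passed with the replicate block. The called clones included 24 named symbols, and 344 of the called clones had the same sign on all 6 mock arrays. Mock RNA carried Cy5 on every array, so a dye bias of a clone remains in these values, and if the ratios follow the order of the titles the 221 would be lower and the 268 higher. Leaving out VF36 mock replicate 2 or D51 mock replicate 1 left 0 calls, Son1 mock replicate 1 left 51, Son1 mock replicate 2 left 9, and either VF36 TMV array raised the count to 736, while either D51 TMV array gave 299; the fit on the mock arrays alone gave 144 and a 2-fold threshold 103.

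Within lines, most calls came from VF36 in the fit over all 12 arrays. There PPO, polyphenol oxidase, was higher after mock inoculation by a log2 change of 1.59 ± 0.35 (SE from the limma fit over 12 arrays, n = 2 arrays, adjusted p = 0.0485). The SD of its 2 arrays was 1.28, and the other PPO clone stood at 1.69 ± 1.35 (SD, n = 2). The value of PPO moved with single arrays: it was 0.68 without VF36 mock replicate 2 and 2.50 without VF36 mock replicate 1. CAT1, a catalase, was lower at -2.13 ± 0.42 by 1 clone (adjusted p = 0.0447), while another CAT1 clone stood at 0.20 ± 0.42 (SD, n = 2). POTPRO1 (-1.49), LOC102583272 (-1.75) and LOC102582373 (-1.68) were lower, and LOC102596994 (1.29), LOC102578519 (1.24), LOC102602779 (1.39), LOC102590793 (1.13) and LOC102580103 (1.03) were higher. Further lower transcripts were LOC102600559, LOC102592687, LOC102587499, LOC102591352, LOC102594986 and LOC102577431, at log2 changes from -1.89 to -1.55. The clone of LOC102587499 called over 3 lines stood at 0.40 ± 0.28 (SD, n = 2) in VF36, opposite to the clone called there (-1.75). The VF36 count was 207 of 8554 clones, 84 higher and 123 lower. With the replicate block the VF36 count fell below that after scaling. Every sign turns if the arrays are inverted, and the count was 12 after scaling, 33 with array weights and 0 in the fit on those 2 arrays alone (1831 clones at an unadjusted p under 0.05), where Son1 had 11 and D51 0. Leaving out any 1 of the 12 arrays moved it: to 4 without VF36 mock replicate 1, 0 without VF36 mock replicate 2, 870 without either VF36 TMV array, 1 without any D51 array, 10 without either Son1 mock array and 5 without either Son1 TMV array.

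In D51 and Son1 named genes did not pass. In D51 the called clones were the unnamed 147665 (6.35-fold higher) and 159381 (3.19-fold higher), and in Son1 the unnamed 142551 (8.68-fold higher) and 132346 (6.35-fold higher). LOC102599567 had the largest change among the extreme named transcripts of D51, 8.11-fold with adjusted p = 0.132, but its 2 arrays stood at log2 4.70 and 1.34, and it was 6.24-fold in Son1 (adjusted p = 0.204). SKT3 stood at -1.27 in D51 (adjusted p = 0.132). In Son1 HPL, hydroperoxide lyase of the oxylipin pathway, stood at -0.85 (adjusted p = 0.177) and STWRKY8, a WRKY transcription factor, at 1.73 (adjusted p = 0.238). The counts were 2 of 7567 clones in D51 and 2 of 8466 in Son1, with 1184 and 1058 at an unadjusted p under 0.05. With the replicate block neither line had a call. All signs turn if the arrays are inverted. The D51 count was 135 without D51 mock replicate 2, 3 without either VF36 mock array and 0 without any of the other 9 arrays. The Son1 count was 23 without either D51 mock array, 3 without either VF36 mock array, 1 without either D51 TMV array, 0 without either VF36 TMV array or either Son1 mock array and 2 without either Son1 TMV array.

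The second comparison asked what the virus added to mock inoculation. No transcript passed in the fit over all 12 arrays. The named gene with the highest t over 3 lines was POTPRO1, with a log2 difference of 0.66 ± 0.13 (SE, n = 6 arrays, adjusted p = 0.367, above 0 on 6 of 6), opposite to its value on the mock arrays. LOC102589596 stood at 0.93, LOC102577570 at 0.60, LOC102586427 at 0.49 and LOC102578876 at 0.49. Averaged over its clones, LOC102586427 fell below 0 instead. PURM, an enzyme of purine synthesis, stood at -0.39 ± 0.10 (adjusted p = 0.368, below 0 on 6 of 6), followed by LOC102578519 (-0.46), LOC102590793 (-0.45), LOC102596994 (-0.41) and LOC102588286 (-0.36). In D51, FLS, flavonol synthase, had a log2 difference of -1.49 ± 0.26 (SE, n = 2 arrays, adjusted p = 0.645), and its value was 0.12 in VF36 and 0.21 in Son1. The other FLS clones stood at -0.06 and -0.38 in D51.

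With limma 0 of 6877 clones passed over 3 lines, 0 of 7351 in VF36, 0 of 8520 in D51 and 0 of 8122 in Son1, and 775, 680, 481 and 291 had an unadjusted p under 0.05. If the TMV arrays hold mock over TMV, the counts stay and every sign turns, for example to -0.66 for POTPRO1 and 0.39 for PURM. Dye bias also remains here. In VF36 the fit on its 2 TMV arrays alone called 26 clones (10 higher and 16 lower) and the fit with no filter 4. Clones passed in VF36 and over 3 lines without VF36 TMV replicate 1, whose spots agreed least, and also without VF36 TMV replicate 2. The VF36 values then rest on 1 array with a spread taken from the other groups, so these calls are no evidence of a TMV response. VF36 TMV replicate 2 had the widest spread over clones of the TMV arrays (0.786) and mirrored VF36 mock replicate 1 (r = -0.843). The same limit of 1 array holds for the call in Son1 without Son1 TMV replicate 1.

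The third comparison set TMV against untreated leaves through the mock RNA. Here STWRKY8 stood 3.03-fold above untreated leaves, at a log2 difference of 1.60 ± 0.40 (SE, n = 12 arrays, adjusted p = 0.271), in 5 of 6 pairs of arrays, and its other clone stood at 1.57 ± 0.41. LOC102599567 (2.59), LOC102598951 (1.86), LOC102577856 (1.19) and LOC102589596 (1.16) were the other named transcripts with the highest t. LOC102577613 stood at -1.06 ± 0.20 (adjusted p = 0.171) and was below 0 in 6 of 6 pairs, and LOC102583272 (-1.21), LOC102582373 (-1.03), LOC102582822 (-1.01) and LOC102587142 (-0.67) were the other lowest. In D51 STWRKY8 stood 5.57-fold higher (adjusted p = 0.520) and LOC102599567 14.6-fold higher (adjusted p = 0.509), on D51 mock arrays with means of 1.40 ± 1.52 and 3.02 ± 2.37 (SD, n = 2), so that both folds move with 1 array, and in Son1 LOC102598951 stood 7.14-fold higher (adjusted p = 0.540). Read as Cy5 over Cy3 these 3 were 1.26-fold (adjusted p = 0.870), 4.52-fold (adjusted p = 0.374) and 5.85-fold (adjusted p = 0.316) higher.

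Under this reading 0 of 6528 clones passed over 3 lines, with 662 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0672, and 0 passed in any line, with 180 in VF36, 612 in D51 and 501 in Son1 at an unadjusted p under 0.05. The answer depends on the direction of the TMV arrays. Under a wrong reading the comparison sets mock against both untreated and TMV leaves, so its values and calls can hold a mock effect. Read as Cy5 over Cy3, 550 clones passed over 3 lines (263 higher and 287 lower), 839 in VF36 and 0 in D51 and Son1 (1006 and 787 at an unadjusted p under 0.05). LOC102577613 then stood at -1.53 (adjusted p = 0.0137), LOC102582822 at -1.48 (adjusted p = 0.0244) and LOC102582373 at -1.18 (adjusted p = 0.0273), LOC102589596 turned to -0.70 and STWRKY8 stood at 0.25. LOC102599567 (1.30), LOC102577856 (1.03), LOC102598951 (0.91), LOC102583272 (-0.87) and LOC102587142 (-0.092) kept their sign and did not pass. Ratios in the order of the titles would keep the 0 calls and turn every sign of the reading used. Leaving out D51 mock replicate 2 gave 74 calls over 3 lines and 18 in D51 under the reading used, and scaling gave 6 over 3 lines; without VF36 mock replicate 1 the count over 3 lines was 2 and without VF36 TMV replicate 2 it was 3. Without VF36 TMV replicate 1 VF36 had 3 calls, without VF36 TMV replicate 2 it had 5, and without Son1 TMV replicate 1 Son1 had 1.

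The lines were compared by a test of the difference itself, in which a dye bias shared by the lines cancels. In the mock response the largest F among named genes belonged to LOC102577768, with a mean log2 ratio of -0.60 in VF36, 0.40 in D51 and 0.88 in Son1 (adjusted p = 0.293). LOC102590108 stood at -1.39 ± 0.12 in VF36, 0.83 ± 1.45 in D51 and 1.94 ± 1.52 in Son1 (SD, n = 2 each, adjusted p = 0.293), and LOC102596783, LOC102591352 and LOC102577637 followed. In the TMV response the largest F values were those of LOC102593050 (0.81 in VF36, -0.58 in D51 and -0.29 in Son1), FLS, LOC102583272, LOC102594309 and LOC102577553 (adjusted p = 0.994 for each). With limma 0 of 7381 clones passed for the mock response and 0 of 6877 for the TMV response, with 1093 and 174 at an unadjusted p under 0.05. The other reading of the TMV arrays or an inversion of all arrays turns the signs and leaves both counts. Without either VF36 TMV array 6 clones passed for the mock response and without D51 mock replicate 2 it was 5. For the TMV response 4 passed without VF36 TMV replicate 1, 1 without VF36 TMV replicate 2 and 1 without Son1 TMV replicate 1.

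**Figure D3:**
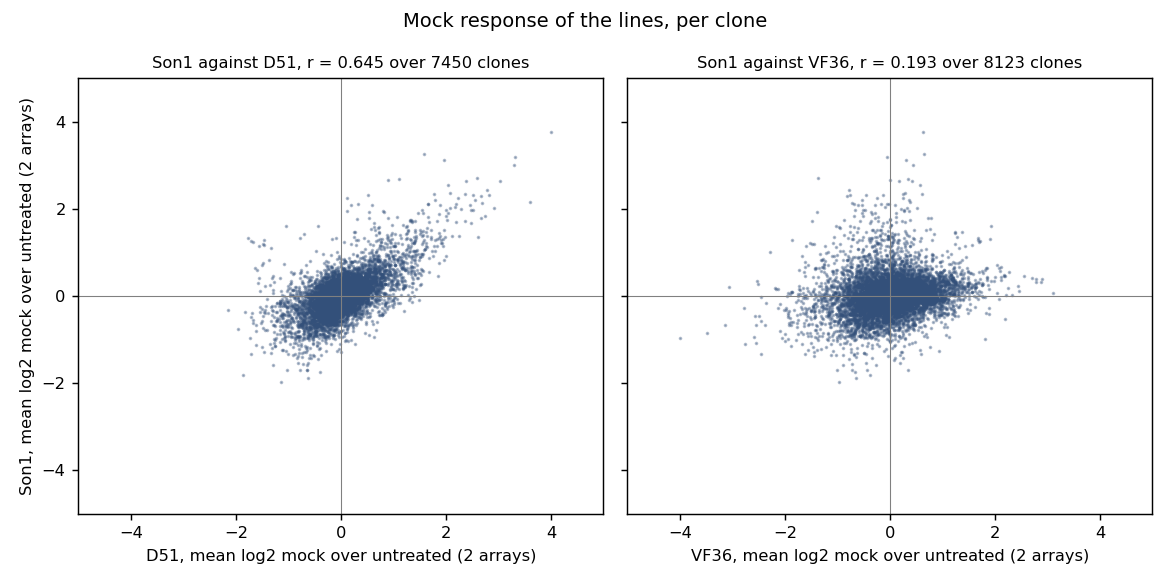
Mean log2 ratio of mock over untreated per clone in Son1 (vertical axis) against D51 (left) and VF36 (right), where each point is a clone and each value the mean of 2 arrays. The correlation across clones is 0.645 over 7450 clones with D51 and 0.193 over 8123 clones with VF36.

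Across clones, the mock responses of D51 and Son1 correlated with r = 0.645, and 413 of the 414 clones with an unadjusted p under 0.05 in both lines had the same sign (151.1 expected in both from independent lists). VF36 correlated with r = -0.08 to D51 and 0.193 to Son1. In both VF36 and Son1 299 clones had an unadjusted p under 0.05 (288.7 expected from independent lists), and 265 of them had the same sign. In both VF36 and D51 254 clones did (334.9 expected from independent lists), and 154 of them had the same sign. The p-values of the lines come from the same fit and share the estimated spread of a clone, so these lists are not independent. The expected numbers are therefore no measure of chance. A dye bias shared by the lines can also give a clone the same sign in both. By array, VF36 mock replicate 1 had r between -0.31 and 0.214 with the 4 mock arrays of D51 and Son1, and VF36 mock replicate 2 between 0.056 and 0.387. The 2 mock replicates within a line had r = 0.488 in VF36, 0.358 in D51 and 0.374 in Son1. For TMV against mock r was 0.442 between VF36 and Son1, 0.297 between D51 and Son1 and -0.055 between VF36 and D51 under either reading. No order of the lines is read from these, since the 4 pairs of VF36 and Son1 TMV arrays had 0.548 (VF36 TMV replicate 2 with Son1 TMV replicate 1), 0.171, 0.021 and -0.104 and those of D51 and Son1 between 0.093 and 0.237. For TMV against untreated, which uses the same mock arrays, D51 and Son1 correlated with r = 0.637 under the reading used and 0.458 under the other, and VF36 with r = 0.013 and 0.012 (other reading -0.117 and 0.395). Clones are not independent replicates, and the F test above called no difference.

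Gene groups could be described only in part, because few clones carry symbols and the fixed lists, largely written as protein names, were matched to symbols alone. Measured clones of PPO, CAT1 and GAPDH, for example, matched no fixed list. Of the fixed lists, early transcription factors held 2 measured clones, both of STWRKY8, and both passed when adjusted over the list alone, in each of the 3 comparisons over 3 lines, while 0 passed over all clones. Within lines both passed over the list alone in D51 and Son1 for mock against untreated and TMV against untreated, 0 in VF36 (median -0.35 for mock against untreated) and 0 in any line for TMV against mock. With 2 clones of 1 gene this adjustment is slight, and the third comparison is built from the other 2. Over 3 lines 2131 of 7381 clones had an unadjusted p under 0.05 with limma for mock against untreated. The numbers were 775 of 6877 for TMV against mock and 662 of 6528 for TMV against untreated. Read as Cy5 over Cy3, the 2 clones stood at 0.25 and 0.17 for TMV against untreated (unadjusted p = 0.546 and 0.691). The salicylic acid list held 2 clones of PR1B, a pathogenesis-related protein, at -1.20 ± 0.44 and 0.10 ± 0.14 (SE) for mock against untreated, and 1 passed when adjusted over the list alone. Calcium and kinase signalling had 1 clone measured over 3 lines, of the calcium-dependent protein kinase CDPK2, at 0.29 for mock against untreated and 0.44 for TMV against untreated (0.13 read as Cy5 over Cy3), neither past the threshold over all clones. The virus resistance list matched only TOM20, a mitochondrial import receptor caught by its symbol, at 0.14. The list of vascular markers held 1 clone, of the sucrose transporter SUT2, of the comparisons over 3 lines measured only in TMV against mock (-0.19). The other fixed lists matched no measured clone by symbol, which does not mean that their genes were not measured.

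Among the added lists, 6 of 11 clones of wound and defence proteins passed when adjusted over the list alone for mock against untreated and 0 over all clones. They were both clones of STWRKY8 (0.93 and 0.87), both of PPO (0.66 and 0.58), 1 of HPL (-0.39) and 1 of PR1B (-1.20). Of all clones 2131 of 7381 had an unadjusted p under 0.05 with limma in this comparison. Camera gave an unadjusted p of 0.325 for the list. The 7 measured clones of membrane pumps and transporters had a median of -0.21 after mock inoculation, and SKT3 (-0.80) passed both over all clones and when adjusted over the list alone. The 12 clones of the methionine and methyl cycle had a median of -0.29, those of antioxidants 0.10, those of carbohydrate and energy metabolism 0.11 and those of flavonoid and shikimate enzymes -0.01. With camera 0 of 60 tests passed and 8 had an unadjusted p under 0.05, against 0 with an estimated correlation (smallest adjusted p = 0.0868, for the methionine and membrane lists in TMV against mock of D51; adjusted p = 0.972 with an estimated correlation). The number that passed was 5 without D51 mock replicate 1, 3 without D51 mock replicate 2, 3 without D51 TMV replicate 2 and 1 without Son1 TMV replicate 2.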

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

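The tests of dye bias, of shared RNA and of single array pairs below were chosen after the correlations had been seen, and the counts of other groupings of the arrays were fixed before they were run. Over the 6 arrays of a kind, 70 sets of values were screened for an array far from the others, 8 stood out and 3.5 would by chance. VF36 TMV replicate 1 had a correlation of paired spots of 0.286 against at least 0.712 on the other TMV arrays. VF36 TMV replicate 2 stood apart in its median (0.043), in LOC102580103 (-1.06), LOC102582711 (-0.61), LOC102577613 (0.83) and LOC102582822 (1.58). D51 mock replicate 2 had 7753 clones with a value against at least 8629 on the other mock arrays, and D51 mock replicate 1 stood apart in LOC102577613 (-1.94).

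The ratios of VF36 mock replicate 1 and VF36 TMV replicate 2 mirrored each other, with r = -0.843 across clones, although the labels list different extracts. A dye bias common to all arrays is argued against as the whole cause, since VF36 mock replicate 1 correlated with the mean of the 4 D51 and Son1 mock arrays at r = -0.147. Whether both arrays held the same pair of RNA samples cannot be told apart from a state of the VF36 mock plants, because VF36 mock replicate 2 also mirrored VF36 TMV replicate 2, at r = -0.576, less than the pair itself. A difference of the VF36 line stays open as a biological explanation and was not tested. Leaving out both arrays gave 18 calls for mock against untreated in VF36.

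On all 12 arrays 174 clones had opposite signs between mock and TMV arrays and 3 had the same sign, and on the 8 arrays of VF36 and Son1, which list no shared mock extract, the numbers were 522 and 18. A dye bias under Cy5 over Cy3 would favour the same sign, so by itself it does not give the 174. That follows from how the pattern was defined, and the same counts were used to choose the reading. It is therefore no evidence against Cy5 over Cy3. A dye bias under channel 1 over channel 2 may contribute, but the median correlation of mock and TMV arrays from different lines was -0.081, near 0, which keeps it open. In D51, where the mock extract is shared, the replicate differences of the 2 kinds of array correlated with r = -0.26, and groups of different lines, which list no shared extract, had values between -0.569 and 0.458, so such a value arises without sharing. An order in which mock leaves lie between untreated and TMV leaves, read as Cy5 over Cy3, stays open as a biological explanation and was not tested.

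The mock responses of D51 and Son1 resembled each other (r = 0.645) more than that of VF36 (r = -0.08 and 0.193), but much of the contrast lay in VF36 mock replicate 1, whose median r with the 4 mock arrays of D51 and Son1 was -0.138. For VF36 mock replicate 2 that median was 0.256, inside the range of the D51 and Son1 pairs, which leaves open whether 1 VF36 array makes the difference and whether a dye bias common to all arrays contributes. A single pair of arrays is argued against as the whole cause, since beside the pair at 0.685 the other 3 pairs of D51 and Son1 mock arrays had a median r of 0.404. A larger share of D51 mock replicate 1 and Son1 mock replicate 1 stays open, as the 1 pair without either had r = 0.122. The pairs across these lines at 0.685, 0.451 and 0.404 lay above the replicates within D51 (r = 0.358) and Son1 (r = 0.374). Replicates within VF36 had r = 0.488. A component common to the arrays therefore cannot be told apart from a likeness of the 2 lines. A difference between lines stays open too, and limma's F test of it called 0 clones, with 1093 at an unadjusted p under 0.05.

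For mock against untreated over 3 lines the 489 calls were exceeded or equalled by 1 of 32 turns of signs of the mock arrays, the real one. The highest other, with VF36 mock replicate 1 turned alone, gave 116. Many turns set the 2 replicates of a line against each other, which raises the fitted spread and lowers the count. The turns therefore cannot tell a response shared by the lines from replicates that resemble each other within lines, and a dye bias is not excluded. For TMV against mock 0 clones were called, so all 32 turns reach that count by design (highest other 0) and it decides nothing. The 775 clones at an unadjusted p under 0.05 were reached by 1 of the 32 turns, the real one, and the highest other gave 608. The same limit of replicates turned against each other holds for that number, and a dye bias is not excluded. For TMV against untreated 0 clones were called as well, so 100 of 100 splits of the arrays within lines reach that count by design, with a highest other of 146. Of the same splits 14 gave at least the 662 clones with an unadjusted p under 0.05, and the highest other gave 1588, so chance cannot be excluded. The split with 146 calls points to a structure of the samples: it kept the mock arrays of D51 and Son1 apart from their TMV arrays, as the real grouping does, and exchanged 1 mock and 1 TMV array of VF36, so it is no measure of chance for those 2 lines. Read as Cy5 over Cy3, the 550 calls were reached by 1 of 100 splits, the real one, and the highest other gave 1. Splits that join VF36 TMV replicate 2 with VF36 mock replicate 1 or 2 join arrays that mirror each other (r = -0.843 and -0.576), which raises the spread. By line only VF36 had calls under that reading, so the splits are no measure of chance for a difference shared by the lines. A dye bias, which adds up if that reading is wrong, is not excluded. Neither is a mock effect, which the comparison then holds in place of TMV against untreated. Single arrays were not left out under that reading.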

How the results depend on the processing

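Array weights, spots tested singly and the pair of VF36 arrays left out were chosen after seeing the data, as were the signs used for the TMV arrays. Centring, the filter to clones on all 12 arrays, the robust prior, the random replicate block and averaging clones of a symbol kept all clone counts within 1.5 times; the cause of the changes below was not tested. No change in the calls of TMV against mock or of the line differences came from the replicate blocks. With the replicate block the calls for mock against untreated were 289 over 3 lines, 9 in VF36, 0 in D51 and 0 in Son1; the block by line left 0 for TMV against untreated. In D51 the number marks a shared mock extract and elsewhere only a number, with correlations of same-numbered deviations between -0.569 and 0.458 over 15 pairs of groups. Scaling gave 12 in VF36, 1 in Son1 and 6 for TMV against untreated over 3 lines. With no filter D51 had 0 for mock against untreated and VF36 4 for TMV against mock. In fits on the arrays of the contrast alone mock against untreated gave 144 over 3 lines, 0 in VF36, 0 in D51 and 11 in Son1, and TMV against mock 26 in VF36. A 2-fold threshold left 103 over 3 lines for mock against untreated, 61 higher and 42 lower. The other reading of the TMV arrays gave 550 and 839 for TMV against untreated over 3 lines and in VF36. Array weights gave 33 in VF36, 0 in D51 and 9 in Son1 for mock against untreated. Spots tested singly gave 802 over 3 lines, 0 in D51 and 0 in Son1, from more tests. Leaving out VF36 mock replicate 1 and VF36 TMV replicate 2 together gave 18 in VF36, 0 in D51 and 1 in Son1 for mock against untreated, 3 over 3 lines and 7 in VF36 for TMV against mock, 2 over 3 lines for TMV against untreated and 1 for line differences in the TMV response.

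Leaving out each array in turn, where a lone array is assumed to vary like the other groups, moved mock against untreated over 3 lines between 0 and 736, VF36 between 0 and 870, D51 between 0 and 135 and Son1 between 0 and 23. TMV against mock moved between 0 and 6 over 3 lines, 0 and 184 in VF36 and 0 and 1 in Son1, and stayed at 0 in D51. TMV against untreated moved between 0 and 74 over 3 lines, 0 and 5 in VF36, 0 and 18 in D51 and 0 and 1 in Son1. Line differences moved between 0 and 6 for the mock response and 0 and 4 for the TMV response, and list tests between 0 and 5. In VF36 the 207 calls fell to 4 without VF36 mock replicate 1, 0 without VF36 mock replicate 2, 10 without either Son1 mock array, 5 without either Son1 TMV array and 1 without any D51 array, and rose to 870 without either VF36 TMV array.

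Under the other reading of the TMV arrays the named values of TMV against mock turned to -0.66 (POTPRO1), -0.60 (LOC102577570), -0.93 (LOC102589596), -0.49 (LOC102586427), -0.49 (LOC102578876), 0.39 (PURM), 0.46 (LOC102578519), 0.36 (LOC102588286), 0.41 (LOC102596994) and 0.45 (LOC102590793), and LOC102589596 in TMV against untreated to -0.70. With clones of a symbol averaged, LOC102587499 turned to -0.28 for mock against untreated and LOC102586427 to -0.041 for TMV against mock. Of the values of named genes under the alternatives other than left-out arrays, 176 of 209 kept direction and call for mock against untreated over 3 lines and 86 of 175 in VF36, and with single arrays left out 124 of 228 and 33 of 192. List tests were run on clones with a value on every array used and were not run without a filter, as the filter to all 12 arrays anew, with a random block, a block by line, robust prior, 2-fold threshold, averaged symbols, array weights or single spots. Signal over background was not used here, so its limit is unknown.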

Other observations

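METK1, S-adenosylmethionine synthetase, was looked at after its values were seen. Its 7 measured clones had mean log2 ratios of mock over untreated between -1.26 and -0.96 in VF36 (n = 2 arrays), between -0.20 and 0.08 in D51 and between -0.20 and 0.23 in Son1, with SDs up to 0.375, 1.01 and 0.343. Over 3 lines the lowest clone stood at -0.52 ± 0.20 (SE, adjusted p = 0.126). On the TMV arrays the same clones had means between 0.38 and 0.68 in VF36, -0.72 and -0.41 in D51 and 0.18 and 0.36 in Son1, with signs that turn under the other reading. The 2 replicates disagreed there, with SDs of 0.775 to 1.30 in VF36, 0.668 to 0.961 in D51 and 0.585 to 0.984 in Son1. The clones of 1 gene are not independent of each other, and the list that holds METK1 did not pass.

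The 5 measured clones of GAPDH, a glycolytic enzyme, lay between 0.16 and 0.28 for mock against untreated over 3 lines. The WRKY factor STWRKY8 had a mean log2 ratio of mock over untreated of 1.40 ± 1.52 in D51, 1.73 ± 0.09 in Son1 and -0.36 ± 1.13 in VF36 (SD, n = 2 arrays each), and its other clone had 1.41 ± 1.22, 1.53 ± 0.80 and -0.34 ± 1.09. For TMV against untreated the replicates of VF36 correlated with r = -0.535 across clones under the reading used and 0.738 under the other, whereas those of D51 had 0.436 and 0.261 and those of Son1 0.207 and 0.361. The mirror of VF36 mock replicate 1 and VF36 TMV replicate 2 (r = -0.843) lowers the first VF36 value and raises the second, so they do not decide the reading.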
